A study of Mus musculus with 4 samples.

How the data were processed

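RNA from laser-captured epidermis of glabrous mouse hindpaw skin was amplified by the NuGEN pico protocol, labelled with biotin and hybridised to 4 whole-transcript arrays, per the labels' protocols. The design text gives 2 pools of 3 noggin transgenic animals and 2 pools of 3 BMP4 transgenic animals. The replicates are therefore pools of different animals, and the spread between them is a spread between pools. The submitters' processing notes name Affymetrix Expression Console and RMA, with no version or settings. The deposited values are log2 probe set intensities from that processing by the authors, and they have near-equal quartiles on all arrays. RMA corrects the background, quantile-normalizes the arrays and summarizes the probes of a probe set, which removes any difference in overall signal between arrays and compresses the changes of dim probe sets. Scanner files, scan dates and hybridisation batches were not used here, and detection above background is unknown. For arrays, the number of arrays limits the precision.

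All 35556 probe sets were tested. No identifier marked a control probe set, so 0 were removed. The platform table names 23410 of them, 21789 with 1 gene symbol and 1621 with several, and the other 12146 are unnamed here. Of the probe sets with 1 symbol, 21698 matched the GRCm38.p6 gene table by Entrez identifier. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 19938 genes, 999 of them with more than 1 probe set.

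The difference between noggin and BMP4 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, 2 residual degrees of freedom and 2.08 prior degrees of freedom). Values of p were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Errors are SDs of 2 arrays, and folds are 2 to the power of the difference of group means. Gene lists were tested with camera (preset correlation of 0.01, Benjamini-Hochberg over the 34 of 35 lists with at least 5 measured genes). Camera asks whether a list moves against the other genes, while fry asks whether a list's genes move one way on balance. Of the genes named, the rule gave both transgenes, the 12 genes of smallest p in each direction because none passed the threshold, and up to 4 genes of smallest p from each list. The 4 were named for lists that passed and 2 for the others. Predicted genes were skipped, which left out 2. The lists, this rule, the tests and the alternatives were fixed before the data were examined, except the tests and the 2 alternatives said to be later.

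The code was tested on simulated data for the noggin against BMP4 comparison, over 35556 probe sets with the real means, a spread drawn from the fitted prior and 200 changed probe sets in each of 20 runs. In these simulated data limma called 3.3% of those changed by 1 log2 unit, 70.8% at 2, 85.9% at 3 and 94.3% at 4, with 7.25 false calls per run on average. These shares depend on the 200 planted changes, since many strong changes loosen the Benjamini-Hochberg cutoff. On the real arrays Skint3, at -3.35, had an adjusted p of 0.451 (limma). The shares therefore do not give the power of the real comparison. Camera called a list of cell cycle genes shifted by 0.4 in 20 of 20 runs and on average 0.05 other lists, in simulated data with no correlation between genes.

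The replicate numbers did not pair the arrays. The deviations of same-numbered arrays from their group means correlated at -0.12, and the labels tie no number to a litter or day. The alternatives were the replicate number as a block, a trend or robust prior in eBayes, leaving out dim probe sets, median centring, further quantile normalization, cyclic loess, the mean of all probe sets of a gene, other thresholds, leaving out each array, an estimated correlation in camera and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.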

Results

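Gene expression was measured in the epidermis of mice that overexpress one of 2 secreted proteins under the K14 promoter, which drives expression in basal keratinocytes. One line overexpresses BMP4, a bone morphogenetic protein, and the other overexpresses noggin, an extracellular protein that binds and blocks BMPs. The question posed by the design was how the epidermal transcriptome differs between skin with raised BMP ligand and skin with raised BMP antagonist. Epidermis of the hairless hindpaw skin was cut out of sections by laser, with 8 to 10 strips from each animal. RNA of 3 animals was pooled for each array, so that the 6 animals of each line gave 2 noggin arrays and 2 BMP4 arrays. No array of non-transgenic skin was analysed here, and every difference is therefore between the 2 transgenic lines, given as noggin minus BMP4 on the log2 scale. Log2 values were measured for 35556 probe sets, and the array medians lay between 6.04 and 6.06. Across the 19938 named genes, which are not independent replicates, the arrays correlated with r between 0.985 and 0.993. The noggin replicate 1 array correlated at 0.993 with BMP4 replicate 2 and at 0.992 with the other noggin array. BMP4 replicate 1 stood farthest from the others, with 43 genes more than 1 log2 unit above and 44 genes more than 1 log2 unit below all 3 other arrays, against 1 to 13 such genes in either direction in the other arrays.

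Neither transgene stood out as an overexpressed transcript. Nog, measured by probe set 10389752, had a log2 value of 5.95 ± 0.048 (SD, n = 2) in noggin epidermis and 6.09 ± 0.062 (SD, n = 2) in BMP4 epidermis, a difference of -0.13 with a 95% interval from -0.39 to 0.12 (limma, adjusted p = 0.946), and both noggin arrays lay below both BMP4 arrays. Bmp4, measured by probe set 10419261, had a log2 value of 7.81 ± 0.063 (SD, n = 2) in noggin epidermis and 8.13 ± 0.14 (SD, n = 2) in BMP4 epidermis. Bmp4 was 1.24-fold higher in the BMP4 arrays, with both BMP4 arrays above both noggin arrays and an adjusted p of 0.874 in limma. Neither passed when adjusted over the list alone, the 2 transgenes, where the smaller p was 0.099. Which part of each transcript the transgenes carry is not given in the sources used here, and a probe set outside that part does not register the transgene, so the Nog and Bmp4 values do not check the labels.

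No single gene passed the threshold in the comparison of noggin with BMP4 epidermis. Among the genes with the smallest p, Chil1, S100a9, Cxcl9 and Saa1 had the largest folds on the noggin side, and Skint3, Btbd10 and S100a3 on the BMP4 side. Limma called 0 of 35556 probe sets at an adjusted p below 0.05, the smallest adjusted p being 0.451. At an unadjusted p below 0.05 it gave 1994 probe sets, 1029 higher and 965 lower in noggin, where chance alone gives about 1778. Among the 19938 named genes the same fit gave 854, or 4.3%, below the 997 that chance gives. A fit on the mean of all probe sets of each gene gave 1163, above 997. Whether the count lies above or below chance therefore depends on the fit. The groups did not overlap in 33.6% of genes, and chance gives 33.3%. In 115 genes the group means differed by at least 1 log2 unit, 54 of them higher in noggin and 61 lower. An exact permutation test of one gene cannot go below a two-sided p of 0.333 with 2 arrays against 2, so the genes below are named by their rank and none is called. Leaving out 1 array moved the difference by more than 1.5 times for 0 of these 24 genes and for 47 of the 107 genes named in all beside the transgenes. The 24 were picked for a small p on these same arrays, which favours a small spread within groups, so that 0 lends them no support.

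Among the 12 genes with the smallest p on the noggin side, Chil1, a chitinase-like protein, was 4.67-fold higher, with 8.87 ± 0.28 (SD, n = 2) in noggin and 6.65 ± 0.41 (SD, n = 2) in BMP4. S100a9, a subunit of the alarmin calprotectin, was 3.70-fold higher, at 9.07 ± 0.22 against 7.18 ± 0.33. Cxcl9, an interferon-induced chemokine, was 3.02-fold higher, and Saa1, an acute-phase apolipoprotein, 2.64-fold. The BMP4 value of Saa1, 4.01, lies below the lower quartiles of the BMP4 arrays, 4.72 and 4.71. Detection is unknown there, so the size of that fold is uncertain. The lipoxygenase Alox8 was 1.86-fold higher, the lipid droplet protein Plin2 1.69-fold, the stefin-family gene Csta3 1.81-fold and the GABA receptor subunit Gabrp 1.91-fold. The remaining 4 genes were Nudt11 at 1.96-fold, Dph6 at 1.75-fold, Cdc42ep3 at 1.72-fold and Prkcq at 1.51-fold. Adjusted p over all 12 lay between 0.636 and 0.701 (limma).

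Among the 12 genes with the smallest p on the BMP4 side, Skint3, a member of an immunoglobulin-like family expressed in skin and thymus, was 10.2-fold higher in BMP4, at 7.22 ± 0.37 (SD, n = 2) against 3.87 ± 0.11 (SD, n = 2) in noggin. The noggin value lies below the lower quartile of both noggin arrays, 4.71, where detection is unknown, so the size of that fold is uncertain. Btbd10 was 7.85-fold higher, with a noggin value of 4.73 that lies just above that quartile. S100a3, a calcium-binding protein of the hair cuticle, was 3.08-fold higher, at 9.76 ± 0.14 against 8.14 ± 0.16. Foxm1, a transcription factor of mitotic genes, was 1.91-fold higher, and the spindle genes Knstrn and Spag5 were 1.74-fold and 1.59-fold higher. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, was 2.30-fold higher, while its other probe set differed by only -0.18 on the log2 scale. H2-Eb1, an MHC class II chain, was 1.93-fold higher. The other genes were Rps27l at 2.19-fold, Arl3 at 1.67-fold, Igfbp5 at 1.65-fold and Sgcb at 1.60-fold. Adjusted p over all 12 lay between 0.451 and 0.701 (limma). Skint genes, stefins, the type II keratins and the Lce, Sprr and Krtap genes are families of close copies, and probes that bind more than one member could mix their values. Counts of genes in lists that hold several members of a family may then repeat the same signal, which was not checked.

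Gene lists fixed before the data were examined were then compared with all other genes by camera. With the preset correlation of 0.01 between genes, 11 of 34 lists passed an adjusted p of 0.05, 4 lower and 7 higher in noggin. Estimating the correlation from the arrays left 0 of the 34, with a smallest adjusted p of 0.697, and fry also called 0, with a smallest adjusted p of 0.61. At an unadjusted p below 0.05 both gave 0 lists. Under the preset correlation 14 of the 34 lists lay at an unadjusted p below 0.05. Of the 11 lists, 6 also passed in another division of the same 4 arrays. The group shifts that follow describe these 4 pools under the preset correlation.

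**Figure D1:**
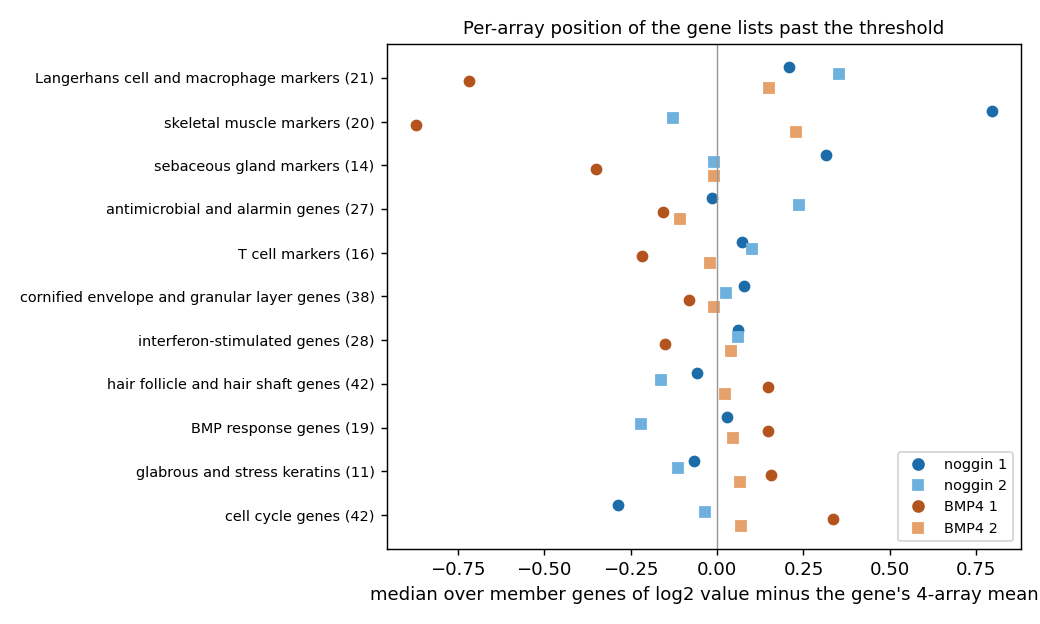
Each row is a gene list that passed camera with the preset correlation, with its number of measured genes in brackets. The horizontal axis gives, for each array, the median over the list's genes of the log2 value minus that gene's mean over the 4 arrays. Circles are replicate 1 and squares replicate 2, blue for noggin and brown or orange for BMP4, spread vertically only to keep them apart. BMP4 replicate 1 lies at one end of the 4 arrays in each of the 11 lists, and its median ranges from -0.87 for skeletal muscle markers to 0.33 for cell cycle genes.

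Cell cycle genes were lower in noggin than in BMP4 epidermis. Of 42 measured genes, 40 had a lower mean in noggin, the median difference was -0.42, and BMP4 was 1.34-fold above noggin at the median. Both noggin arrays lay below both BMP4 arrays for 27 genes, where chance gives 16.7% of genes. The estimated correlation between these genes was 0.486, so they move together and are not separate counts against that share. Ccna2, the S-phase and mitotic cyclin A2, was 8.34 ± 0.14 (SD, n = 2) in noggin and 9.04 ± 0.076 (SD, n = 2) in BMP4. The cytokinesis gene Prc1 was 1.89-fold higher in BMP4, the kinetochore gene Cenpf 1.71-fold and the mitotic kinesin Kif20a 1.60-fold. None of the 42 passed over all genes or adjusted over the list alone, where the smallest p was 0.076. Cell cycle genes had a camera adjusted p of 8.6e-16 with the preset correlation and an adjusted p = 0.697 with an estimated correlation. Their median difference was -0.18 without noggin replicate 1 and -0.26 without BMP4 replicate 1.

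Hair follicle and hair shaft genes were also lower in noggin. Of 42 measured genes, 35 had a lower mean in noggin, with a median difference of -0.15 and a mean of -0.64, and 20 had both noggin arrays below both BMP4 arrays. Krt84, a hair-type keratin, was 5.59 ± 0.17 (SD, n = 2) in noggin and 10.3 ± 1.8 (SD, n = 2) in BMP4, a 27.0-fold difference of means. Krt25, an inner root sheath keratin, was 3.35-fold higher in BMP4, and Cux1, a transcription factor, 1.70-fold. In BMP4 replicate 1, 13 of 44 measured hair keratin-associated protein genes lay more than 1 log2 unit above all 3 other arrays. S100a3 alone passed in limma when adjusted over the list alone (adjusted p = 0.0099), and none passed over all genes. The hair list had a camera adjusted p of 4.2e-07 and an adjusted p = 0.697 with an estimated correlation. Its median difference was -0.08 without noggin replicate 2, -0.24 without noggin replicate 1, -0.14 without BMP4 replicate 1 and -0.26 without BMP4 replicate 2.

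Glabrous and stress keratins were lower in noggin, with 9 of 11 genes below and a median difference of -0.29, and 4 had both noggin arrays below both BMP4 arrays. Krt6a, a keratin of stressed and wounded epidermis, was 3.53-fold higher in BMP4, at 10.6 ± 0.58 (SD, n = 2) against 8.82 ± 0.24 (SD, n = 2). Krt6b was 2.17-fold higher, its usual partner Krt16 1.48-fold and Krt80 1.31-fold. On leaving out 1 array the log2 difference ranged from -1.73 to -0.51 for Krt6b and -0.77 to -0.36 for Krt16. Krt6a was the only gene past the threshold in limma adjusted over the list alone (adjusted p = 0.0494), and none passed over all genes. These keratins had a camera adjusted p of 0.00148 and an adjusted p = 0.697 with an estimated correlation, and a median difference of -0.12 without BMP4 replicate 1.

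BMP response genes were lower in noggin for 18 of 19 genes, with a median difference of -0.21. Msx2, Dlx3, Gata3, Foxn1 and Hoxc13 also belong to the hair list, so this list is not separate evidence from that one. Relative to each gene's mean, the list's median was 0.028 in noggin replicate 1 and -0.22 in noggin replicate 2. It was 0.15 in BMP4 replicate 1 and 0.045 in BMP4 replicate 2. Bambi, a BMP-induced pseudoreceptor, was 1.75-fold higher in BMP4, the homeobox genes Msx2 and Msx1 were 1.71-fold and 1.15-fold higher, and Id3, a target of SMAD signalling, was 1.57-fold higher. Both BMP4 arrays lay above both noggin arrays in these 4 genes, which have the smallest p of the list, and in 8 of the 19, with 1 the other way. Leaving out 1 array gave log2 differences from -1.10 to -0.50 for Bambi, -1.13 to -0.42 for Msx2 and -0.94 to -0.37 for Id3. None of the 19 passed over all genes or adjusted over the list alone, where the smallest p was 0.310. The list had a camera adjusted p of 0.00033 and an adjusted p = 0.704 with an estimated correlation. The camera adjusted p was 0.114 without noggin replicate 2 and 0.107 without BMP4 replicate 1, and the median difference was -0.08 without noggin replicate 2 and -0.32 without noggin replicate 1.

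**Figure D2:**
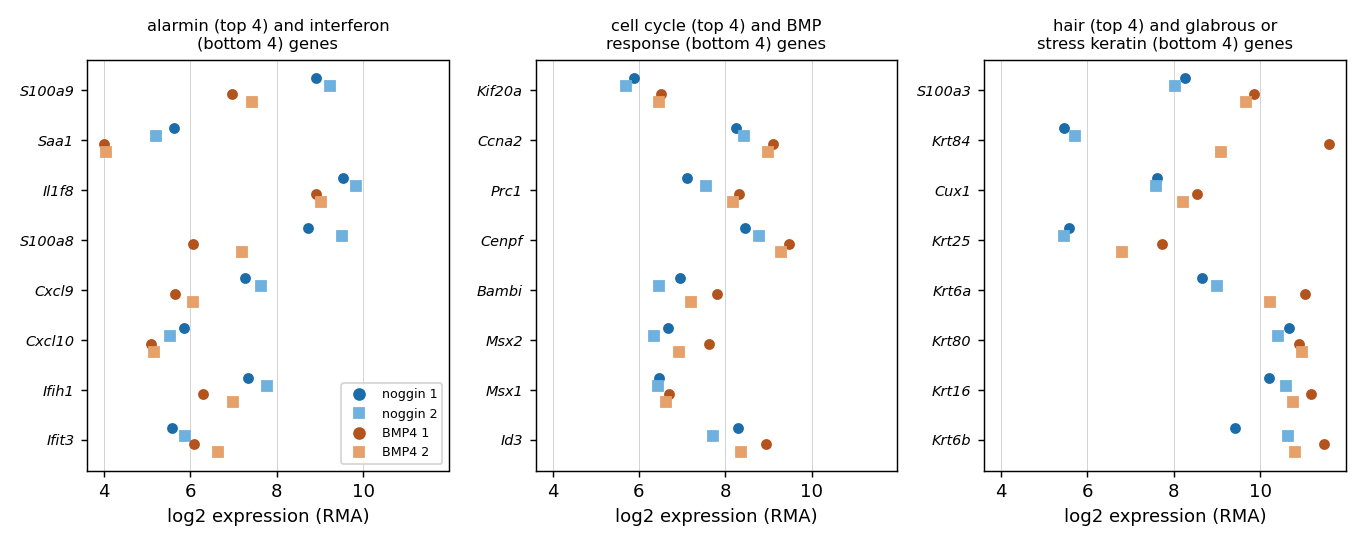
Log2 expression on each of the 4 arrays for the 4 genes with the smallest p in each of 6 lists. Circles are replicate 1 and squares replicate 2, blue for noggin and brown or orange for BMP4. S100a9 lies at 8.92 and 9.23 on the noggin arrays and at 6.95 and 7.42 on the BMP4 arrays, while Krt84 lies at 11.60 and 9.09 on the BMP4 arrays and below 6 on both noggin arrays.

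Antimicrobial and alarmin genes were higher in noggin. Of 27 measured genes, 20 had a higher mean in noggin, the median difference was 0.19, and 14 had both noggin arrays above both BMP4 arrays. S100a8, the partner of S100a9 in calprotectin, was 5.62-fold higher, at 9.11 ± 0.57 (SD, n = 2) against 6.62 ± 0.80 (SD, n = 2). Il1f8, an interleukin-1 family cytokine, was 1.65-fold higher. S100a9, Saa1, Il1f8 and S100a8, 4 of the 27, passed when adjusted over the list alone, with a smallest p of 0.0131, and none passed over all genes. The BMP4 value of Saa1 lies below the lower quartile of those arrays, where detection is unknown. The list had a camera adjusted p of 2.9e-06 and an adjusted p = 0.697 with an estimated correlation. Its median difference was 0.12 without noggin replicate 2 and 0.35 without noggin replicate 1.

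Interferon-stimulated genes were higher in noggin for 22 of 28 genes, with a median difference of 0.10, and 9 had both noggin arrays above both BMP4 arrays. Beside Cxcl9, the chemokine Cxcl10 was 1.47-fold higher and the RNA sensor Ifih1 1.88-fold, whereas Ifit3 was 1.56-fold higher in BMP4. Without 1 array the log2 difference ranged from 0.56 to 1.26 for Ifih1 and -0.91 to -0.37 for Ifit3. Cxcl9 alone passed in limma when adjusted over the list alone (adjusted p = 0.0396), and none passed over all genes. The interferon list had a camera adjusted p of 0.00063, an adjusted p = 0.697 with an estimated correlation, and a camera adjusted p of 0.20 without BMP4 replicate 1. Its median difference was -0.0019 without BMP4 replicate 1 and 0.17 without BMP4 replicate 2. With dim probe sets left out its camera adjusted p was 0.0898.

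Cornified envelope and granular layer genes were higher in noggin for 31 of 38 genes, by a small median of 0.11, and 20 had both noggin arrays above both BMP4 arrays. Rptn, a cornified envelope protein, was 1.63-fold higher, and the small proline-rich genes Sprr2h and Sprr4 were 1.60-fold and 1.44-fold higher. With 1 array left out the log2 difference ranged from 0.39 to 1.02 for Rptn, 0.35 to 1.01 for Sprr2h and 0.30 to 0.75 for Sprr4. Cdsn, the corneodesmosome adhesion protein, was 1.26-fold higher in BMP4. None of the 38 passed over all genes or adjusted over the list alone, where the smallest p was 0.379. The list had a camera adjusted p of 1.6e-05 and an adjusted p = 0.697 with an estimated correlation.

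Markers of several other cell types differed between the groups in the same comparison, which does not show that the share of those cells differed. Some sebaceous gland markers, Scd1 and Dgat2 among them, also belong to the lipid barrier list. All 14 sebaceous gland markers had a higher mean in noggin, with a median difference of 0.40, and in 6 of them both noggin arrays lay above both BMP4 arrays. Their median relative to each gene's mean was 0.31 in noggin replicate 1 and -0.35 in BMP4 replicate 1, and level in the replicate 2 arrays, at -0.008 in noggin and -0.0076 in BMP4. Plin2 and Mgst1, a microsomal glutathione transferase that was 1.68-fold higher, passed when adjusted over the list alone. The fatty acid desaturase Scd1 was 1.47-fold higher and the wax synthase Awat2 1.30-fold, the log2 difference of Scd1 ranging from 0.34 to 0.78 on leaving out 1 array. Langerhans cell and macrophage markers were higher in noggin for 19 of 21 genes, with a median difference of 0.63 that rested largely on BMP4 replicate 1. Without that array the median difference was 0.19, that of H2-Aa was 0.36 and that of Epcam 0.30. Cd207, the langerin of Langerhans cells, was 1.49-fold higher, the MHC class II chain H2-Aa 1.75-fold and Epcam 1.60-fold. The gene of this list with the smallest p, H2-Eb1, went the other way and was the only one past the threshold in limma adjusted over the list alone (adjusted p = 0.0089). All 16 T cell markers had a higher mean in noggin, with a median difference of 0.14. Cd3g, a chain of the T cell receptor complex, was 1.74-fold higher, Ctla2a 1.72-fold, Ptprc 1.79-fold and Cd69 1.39-fold, and none of the list passed when adjusted over the list alone, where the smallest p was 0.230. The log2 difference on leaving out 1 array ranged from 0.43 to 1.17 for Cd3g, 0.50 to 1.07 for Ctla2a and 0.30 to 1.38 for Ptprc. Both noggin arrays lay above both BMP4 arrays in 12 of the 21 Langerhans cell and macrophage, 5 of the 16 T cell and 2 of the 20 muscle markers, and the groups overlapped for Ptprc, Acta1 and Myh1. Skeletal muscle markers, genes of a tissue other than epidermis, were higher in noggin for 19 of 20 genes, with a median difference of 0.62. Acta1, the skeletal actin, was 9.08 ± 0.49 (SD, n = 2) in noggin and 7.99 ± 1.24 (SD, n = 2) in BMP4, and Myh1, Myoz1 and Myl1 were 1.80-fold, 1.38-fold and 1.34-fold higher in noggin. Their log2 differences on leaving out 1 array ranged from 0.22 to 1.96 for Acta1, 0.22 to 1.47 for Myh1, 0.092 to 0.84 for Myoz1 and 0.19 to 0.64 for Myl1. None of the muscle genes passed when adjusted over the list alone, where the smallest p was 0.463.

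The camera adjusted p was 4.2e-07 for sebaceous gland, 5.4e-06 for Langerhans cell and macrophage, 0.00021 for T cell and 1.0e-05 for skeletal muscle markers. With an estimated correlation the adjusted p was 0.697 for sebaceous gland and T cell markers and 0.704 for the other 2 lists. No gene of these 4 lists passed over all genes. The sebaceous gland list had a median difference of 0.14 without BMP4 replicate 1 and 0.24 without noggin replicate 1, and the Langerhans cell and macrophage list 1.06 without BMP4 replicate 2. The T cell list had a camera adjusted p of 0.0588 without BMP4 replicate 1 and a median difference of 0.28 without BMP4 replicate 2. The muscle list had 0.222 without noggin replicate 1 and 0.267 without BMP4 replicate 1, with median differences of 0.17 and 0.11, and 1.11 without noggin replicate 2 and 1.20 without BMP4 replicate 2. The muscle list's per-array medians were 0.79 in noggin replicate 1, -0.13 in noggin replicate 2, -0.87 in BMP4 replicate 1 and 0.23 in BMP4 replicate 2, relative to each gene's mean.

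The 23 other lists did not pass camera with the preset correlation, and no gene in them passed over all genes or adjusted over the list alone. Gene values are log2 differences, followed in parentheses by the range on leaving out 1 array where that moves them by more than 1.5 times. It moved the list median by that much in all 23 lists and changed its sign in 12, with medians from -0.19 to 0.28. Basal keratinocyte genes had a median difference of -0.10 over 19 genes and a mean of 0.03 (camera adjusted p = 0.371), with the hemidesmosome genes Itgb4 and Col17a1 at -0.18 and -0.15. Spinous keratinocyte genes had a median of 0.03 (adjusted p = 0.589), with Krtdap at 0.19 and Ovol1 at -0.13 (-0.18 to -0.082). Epidermal proteases and inhibitors had a median of 0.03 and came closest to the threshold (adjusted p = 0.0744), with the kallikrein Klk6 at 0.68 and the stefin Stfa3 at 1.16 (0.75 to 1.56). That list passed with a trend in the prior (camera adjusted p = 0.0387) and without BMP4 replicate 1 (camera adjusted p = 0.0142). Lipid barrier genes had a median of 0.04 (adjusted p = 0.145), with the fatty acid elongase Elovl6 at 0.58, and sweat gland and eccrine duct genes a median of 0.01 (adjusted p = 0.481), with the carbonic anhydrase Car2 at 0.61 (0.40 to 0.82) and the beta-defensin Defb1 at 0.32 (0.21 to 0.43). The lipid barrier list had 0.0114 without BMP4 replicate 2.

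The signalling lists also did not pass. WNT pathway genes had a median of -0.04 (adjusted p = 0.111), with the secreted inhibitor Wif1 at -0.30 (-0.41 to -0.20) and Wnt10a at -0.22, and a camera adjusted p of 0.0368 without noggin replicate 1 and 0.027 without BMP4 replicate 1. Hedgehog pathway genes had a median of -0.05 (adjusted p = 0.244). In that list Boc was at -0.20 and Hhip, a Hedgehog-binding inhibitor, at -2.14 (limma, adjusted p = 0.874). Hhip was 5.37 ± 0.066 (SD, n = 2) in noggin and 7.51 ± 1.58 (SD, n = 2) in BMP4, with a range from -3.26 to -1.03 on leaving out one array. The median of the Hedgehog list was -0.028 without BMP4 replicate 2. Notch pathway genes had a median of -0.12 (adjusted p = 0.203) that was -0.0078 without noggin replicate 2 and -0.03 without BMP4 replicate 2, with Notch1 at -0.31 (-0.43 to -0.19) and Notch3 at -0.25 (-0.33 to -0.16). BMP ligands, antagonists and receptors had a median of 0.01 (adjusted p = 0.825), with Grem1 at -0.23 (-0.33 to -0.13) and Gdf6 at 0.27 (0.078 to 0.47). FGF and EGF ligands and receptors had a median of -0.01 (adjusted p = 0.923), with Fgf7 at 0.58 (0.28 to 0.88) and Fgf18 at -0.25 (-0.33 to -0.16). Neurotrophic and axon guidance genes had a median of -0.04 (adjusted p = 0.501), with the ephrins Efnb1 at -0.35 and Efnb2 at 0.24. Keratinocyte channels, receptors and neuropeptides had a median of -0.01 and a mean of 0.02 (adjusted p = 0.614), with the bradykinin receptor Bdkrb2 at 0.61 and the neuropeptide gene Calcb at 0.34.

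Immediate early and heat shock genes, a sign of tissue handling, had a median of 0.01 (adjusted p = 0.540), with Fosb at 0.64 and Hspa1a at 0.21. Cytoplasmic ribosomal proteins had a median of 0.02 (adjusted p = 0.718), with Rplp1 at -0.19 (-0.28 to -0.099) and Rps9 at 0.16 (0.099 to 0.23) but -0.22 in its other probe set, and oxidative phosphorylation genes a median of 0.02 (adjusted p = 0.371), with Sdha at -0.23 and Ndufa4 at 0.26 (0.16 to 0.35). Fibroblast and dermal matrix markers had a median of 0.01 (adjusted p = 0.371), with Timp3 at 0.34 and Dpt at 1.05 (0.41 to 1.70). The fibroblast list was lower in noggin without BMP4 replicate 1 (adjusted p = 0.000271) and higher without BMP4 replicate 2 (adjusted p = 2.0e-08). Endothelial and pericyte markers had a median of 0.03 (adjusted p = 0.745), with Cspg4 at -0.23 and Flt1 at -0.29 (-0.41 to -0.18), and were higher in noggin without BMP4 replicate 2 (adjusted p = 0.0449). Schwann cell and neuron markers had a median of -0.05 (adjusted p = 0.371), with Tubb3 at -1.05 and Ncmap at -0.20 (-0.29 to -0.10). Mast cell and granulocyte markers had a median of 0.13 (adjusted p = 0.111), with Tpsab1 at 0.25 (0.12 to 0.38) and Cma1 at 0.17, and an adjusted p of 0.0482 without noggin replicate 1. Merkel cell markers had a median of -0.02 and a mean of 0.01 (adjusted p = 0.923), with the mechanosensitive channel Piezo2 at 0.36 (0.19 to 0.54), though its other probe sets gave -0.15 and 0.01, and Sox2 at 0.16 (0.027 to 0.30). Melanocyte markers had a median of -0.02 and a mean of 0.02 (adjusted p = 0.776), with Pmel at 0.22 (0.11 to 0.34) and Tyrp1 at 0.16 (0.099 to 0.21). Adipocyte markers had a median of 0.01 (adjusted p = 0.962), with Cd36 at 0.47 (0.058 to 0.87) and Lep at -0.19 (-0.33 to -0.056). Red blood cell markers, of which 5 genes were measured, had a median of 0.02 (adjusted p = 0.623), with Car1 at 0.29 (0.032 to 0.56) and Alas2 at 0.16 (-0.0072 to 0.33). In 5 of these lists the signs differed. Camera's direction was lower in noggin for basal keratinocyte genes, against a mean above 0, and higher for the FGF and EGF, channel and receptor, Merkel cell and melanocyte lists, against medians below 0.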

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

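The crossed replicate block and the fit on probe sets with 1 gene symbol were chosen after seeing the data. The count of called probe sets was 0 under each alternative run, including an adjusted p below 0.1, the replicate block (1736 probe sets at an unadjusted p below 0.05), the crossed block (2441), the probe sets with 1 gene symbol (1227) and leaving out any array (1745 to 2455). With the replicate block 11 lists passed camera, the same 11, and the block, on numbers that do not pair the arrays, changed no call. The crossed pairing, tried because same-numbered arrays deviated in opposite directions, also gave 11. The lists called ranged from 10 to 15 on leaving out one array, and 7 of the 11 remained without BMP4 replicate 1, 10 without either noggin array and 11 without BMP4 replicate 2. An estimated correlation left 0 lists and fry left 0, which is the largest dependence found. Camera's unadjusted p also rose where the estimated correlation lay below the preset 0.01. It went from 0.0455 to 0.169 for the mast cell list (correlation 0.0012) and from 0.0263 to 0.128 for the epidermal protease list (-0.034). A larger correlation is therefore not the only source of the rise. In each of the 11 lists that passed, however, the estimated correlation lay above the preset. It ranged from 0.039 for glabrous and stress keratins to 0.855 for Langerhans cell and macrophage markers, with 0.486 for cell cycle genes. How much of the rise in those lists comes from the larger correlation was not tested. The estimated correlation and fry both rest on the 2 residual degrees of freedom, so 0 calls do not show that the lists are level. With an estimated correlation the adjusted p was 0.697 or 0.704 for each of the 11. By fry it was 0.61 for sebaceous gland, T cell, cell cycle, hair, alarmin, cornified envelope and glabrous keratin lists, 0.621 for interferon, 0.664 for BMP response and 0.846 for Langerhans cell and muscle lists. With a trend in eBayes 12 lists passed, the 11 and the epidermal protease list (0.0387). Interferon-stimulated genes reached 0.0898 with dim probe sets left out. Leaving out one array moved the adjusted p from 1.8e-05 to 0.114 for BMP response, 8.1e-06 to 0.20 for interferon, 4.4e-12 to 0.267 for muscle and 3.8e-06 to 0.0588 for T cell lists. The cause was not tested.

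Some lists that did not pass changed direction. On leaving out one array the adjusted p ranged from 0.0698 to 0.247 for adipocyte, 0.697 to 0.923 for BMP ligand, 0.53 to 0.966 for ribosomal protein, 0.0449 to 0.335 for endothelial, 0.503 to 0.715 for FGF and EGF, 2.0e-08 to 0.555 for fibroblast, 0.131 to 0.825 for immediate early, 0.207 to 0.854 for channel and receptor, 0.0562 to 0.715 for Merkel cell, 0.115 to 0.699 for red blood cell and 0.103 to 0.854 for sweat gland lists. The direction also turned for adipocyte markers under the replicate block (0.983), for ribosomal proteins under quantile normalization (0.924) and cyclic loess (0.704), for spinous genes under cyclic loess (0.962), for endothelial (0.713) and FGF and EGF lists (0.685) without dim probe sets, for FGF and EGF and Merkel cell lists by fry (0.992) and for Merkel cell markers with mean probe sets (0.958). Of 1265 alternative values of the 107 genes named by the rule beside the transgenes, 1263 kept their direction. The rule picked these genes by small p on the same arrays, so that count is no independent support. Alas2 ranged from -0.0072 to 0.33 on leaving out one array, and Rps9 was -0.029 with the mean of its probe sets. Nog stayed between -0.18 and -0.089 and Bmp4 between -0.41 and -0.21 on leaving out one array. A group left with 1 array was assumed to vary like the other group. The robust prior does not enter camera and was run for single genes only. Detection over background was not known, so values near the floor have no tested limit.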

Other observations

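The tests in this part were chosen after the results were seen, except the basal keratinocyte test and the strain gene test, whose predictions were written before. The genes named only in this part were chosen after their values were seen. Keratin-associated protein genes, which encode hair shaft matrix proteins, stood apart in one array. Of 44 measured Krtap genes, 13 lay more than 1 log2 unit above all 3 other arrays in BMP4 replicate 1, and 0 did so in any other array. Krtap13 was at 10.6 in that array and between 3.85 and 3.93 in the other 3, and Krtap6-2 at 11.8 against 5.36 to 5.43. Krtap3-3 was also higher in BMP4 replicate 2, with 11.4 and 8.29 on the BMP4 arrays and 4.88 and 4.89 on the noggin arrays. Defb4, a beta-defensin, was at 8.75 in BMP4 replicate 1 and at 4.83 or below elsewhere, and Saa3, an acute-phase gene, was at 8.79 in noggin replicate 2 and at 4.83 or below elsewhere. Rgs2 and Serpinb3c were higher in both noggin arrays by 1.53 and 1.44 on the log2 scale, and Adh6a and Slc38a4 lower, at -2.03 and -1.72, none past the threshold in limma (adjusted p between 0.732 and 0.773).

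The hair genes may mark a true difference in the hair programme or a few strips of hair or nail tissue in one pool. Whether tissue in BMP4 replicate 1 alone accounts for the list median stays open. Without that array the median was -0.14, against -0.15 with all arrays, but BMP4 replicate 2 lay only 0.08 above the nearer noggin pool in the list's median, less than the 0.11 between the 2 noggin pools. Of 3 tests tried earlier, a percentile of 100 among random gene lists and a bootstrap over genes without that array (-0.22 to -0.056) leave out the spread between pools, and a prediction interval from the 2 noggin pools was too wide to decide (-1.29 to 1.07). Of the 34 hair list members other than Krtap genes, 4 (Krt36, Krt86, Krt84 and Dsg4) lay more than 1 log2 unit above every other array in BMP4 replicate 1. The marks for this count, at least 5 for captured tissue and 0 against it, were arbitrary and set after the results were seen. A count of 4 therefore decides nothing.

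The lower cell cycle genes in noggin could come from fewer basal keratinocytes in the captured strips, or from the sex of the pooled animals. Basal keratinocyte genes had a median of -0.10 and a mean of 0.03, with 9 genes higher and 10 lower in noggin. Their median lay 0.33 above the cell cycle median, with a 95% bootstrap interval over genes from 0.13 to 0.50 that excludes the predicted equal fall. Leaving out 1 array moved that difference from 0.13 (0.02 to 0.33) without noggin replicate 1 to 0.46 without BMP4 replicate 2, and the intervals leave out the spread between pools. Per array, the basal minus the cell cycle median was 0.22 and 0.033 in noggin replicates 1 and 2. It was -0.32 and -0.014 in BMP4 replicates 1 and 2. The replicate 2 pools were nearly level, so a smaller share of basal cells stays undecided. Y-linked Eif2s3y was at 4.23 in noggin replicate 2 and between 8.10 and 8.68 in the other 3 arrays, and Xist was highest there at 11.5, so that pool is a candidate for holding females only. Xist was also at 10.6 to 10.9 in the other 3 arrays, so those pools may hold both sexes. Their male share may differ, with Y-linked Kdm5d at 7.76 in BMP4 replicate 1, 6.84 in noggin replicate 1 and 6.32 in BMP4 replicate 2. Without noggin replicate 2 the cell cycle median was -0.52, against -0.42 with all arrays. Noggin replicate 1 lay 0.36 below the nearer BMP4 pool, more than the 0.26 between the BMP4 pools. Noggin replicate 2 was the noggin pool nearer to BMP4, at -0.035 against 0.070 in BMP4 replicate 2. Leaving it out therefore enlarges the shift and rests it on 1 noggin array. Noggin replicate 2 alone does not make the shift, but a difference in sex between the pools is not excluded. An effect of the transgenes was not tested and stays open.

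A set of genes was far lower in both noggin arrays than in both BMP4 arrays. AI506816, skipped by the naming rule as a predicted gene, was at -4.51, Skint3 at -3.35, Btbd10 at -2.97, Mns1 at -1.93 and Ifi202b at -1.83. The MHC genes H2-Eb1 (-0.95) and H2-Ea (-0.56) were lower in noggin while H2-Aa (0.81), H2-Ab1 (0.67) and Cd74 (1.35) were higher. H2-Aa, H2-Ab1 and Cd74 were each lowest in BMP4 replicate 1, and the groups overlapped for H2-Ab1. Cd74 was at 6.72 in that array and at 8.44 in BMP4 replicate 2, so the contrast rests partly on 1 array. Class II genes are usually expressed together. Different inbred strain backgrounds of the 2 lines are a possible explanation, and the strains are not given in the sources used here. In 7 strain-variable genes written down beforehand the median absolute difference was 0.16, at percentile 84.8 of 10000 random matched lists, with Entpd4 at -0.57 and Pttg1, itself a mitotic gene, at -0.65, which leaves the explanation undecided.

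The 4 arrays can be divided into 2 and 2 in only 3 ways, too few for a share under 0.05. The real division gave 1994 probe sets at an unadjusted p below 0.05, and the highest other gave 2143, so that 2 of the 3 divisions reached the real count. The division that set noggin replicate 1 and BMP4 replicate 2 against the others was that highest one. For gene lists the real division called 11 and the highest other 8, so that 1 of the 3 divisions reached the real count. Of the 11 lists, 6 were also called in another division, 3 of them at a smaller camera adjusted p than in the real one. With same-numbered arrays together, BMP response genes had 0.000229 against 0.00033, Langerhans cell and macrophage markers 2.8e-08 against 5.4e-06 and hair genes 0.00112 against 4.2e-07. With noggin replicate 1 and BMP4 replicate 2 together, skeletal muscle markers had 7.2e-11 against 1.0e-05, cell cycle genes 1.4e-07 against 8.6e-16, sebaceous gland markers 0.0029 against 4.2e-07 and Langerhans cell and macrophage markers 0.0275. The 5 called in the real one only were the cornified envelope, glabrous and stress keratin, alarmin, interferon and T cell lists. Most of these came near the threshold elsewhere. With same-numbered arrays together the camera adjusted p was 0.066 for interferon and 0.0783 for alarmin and T cell lists. With noggin replicate 1 and BMP4 replicate 2 together it was 0.0934 for the cornified envelope list. The glabrous keratin list had 0.42 and 0.629 in these 2 divisions.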
